A study of Homo sapiens with 6 samples.

How the data were processed

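Gene expression was measured on 6 single-channel Affymetrix arrays in 786-O cells, an established human line from a renal cell carcinoma. Per the labels, 3 arrays came from cells with a negative control short hairpin RNA (shNC) and 3 from cells with an shRNA against ERCC6L (shERCC6L). Per the labels, shRNA was brought in by lentivirus. The protocol text is the same for all samples and names only the ERCC6L shRNA. Per the labels' protocols, total RNA was extracted with Trizol and 6 ug per sample was turned into biotin-labelled cRNA. Nothing in the labels says whether the replicates are separate cultures or infections, so p-values measure the spread between these samples, which may be technical. The labels also do not say how many hairpins were used.

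The deposited values are linear probe set intensities, 1 per probe set and array, with no value below 0. Per the submitters' processing notes they came from Affymetrix Expression Console. The version, background correction, normalization and summarization are not given in the sources used here. The deposited intensities were already on a common scale: the array medians lay between 60.04 and 61.56, the lower quartiles between 17.05 and 17.86 and the upper quartiles between 216.7 and 225. No array was a copy of another. The table held no detection calls, so the level at which a dim probe set exceeds background is unknown, and the number of arrays limits the precision.

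The value table held 49395 probe sets. Of these, 102 were Affymetrix controls, 44994 had 1 gene symbol in GEO's platform annotation, 1832 had several and 2473 had no gene listed here. Gene numbers of 44967 single-symbol probe sets matched the RefSeq gene table of GRCh38.p14, which changed no symbol. Some genes are not reported here. Intensities were transformed to log2(signal + 16), a pseudocount that understates the fold change of dim genes. For each gene the probe set with the highest mean over all 6 arrays was kept, which gave 18132 genes and set 26862 probe sets aside. All fold changes are on this scale and are given as shERCC6L over shNC unless a fold lower is stated.

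The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, 4 residual and 4.95 prior degrees of freedom) without a block or a filter on dim genes. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. A second count asked for a change of at least 2-fold as well. In data simulated from the real means and spreads, all 50 genes changed by 1 and all 50 changed by 2 on the log2 scale were recovered, as were 98% of those changed by 0.5 and 62% of those changed by 0.25. Of the 193 calls, 6.74% were false. With so few calls the adjusted threshold was stricter than for the real data, so these shares do not carry over to it.

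In all, 36 gene lists were written down before the data were examined, together with the groups, the tests, the rule for named genes and the alternatives. They cover mitosis, anaphase bridges, replication, histones, p53, nucleotide excision repair, apoptosis, MAPK components, ERK-responsive genes, PI3K-AKT-mTOR, hypoxia, glycolysis, oxidative phosphorylation, NF-kB, interferon, stress responses, tRNA synthetases, heat shock, sterols, fatty acids, matrix, epithelial-mesenchymal transition, TGF-beta, YAP-TAZ, integrins, autophagy, NRF2, ribosomal proteins, ribosome biogenesis, housekeeping, small RNA proteins and markers of 5 cell types. For each list the members past the threshold were counted, and the list was tested against all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Camera with an estimated correlation was the alternative for this question. Fry was run as well, which tests whether a list's genes move on balance one way and does not compare them with other genes. In a simulation with independent noise for each probe set, 1 list shifted by 0.2 was called and 0 of the others were. As it held no inter-gene correlation, it does not test whether the preset of 0.01 is adequate.

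The named genes are ERCC6L, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean reached the median level of 6.68 on the log2(signal + 16) scale, and the 4 members with the smallest p from each list past camera's threshold and from the mitosis, anaphase bridge, replication, p53 and MAPK lists. Members named beyond these were chosen after their values were seen. Replicate numbers are shared between the groups in the labels, but same-numbered arrays did not deviate together: the correlations of their deviations from the group means were 0.24, -0.14 and -0.01. They were therefore not treated as pairs.

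The alternatives chosen then were a replicate block, quantile normalization, median centring, leaving out the dimmest genes, averaging a gene's probe sets, testing every probe set, an intensity trend with robust estimation, array weights, a pseudocount of 1, other thresholds and leaving out each array. A covariate for array background, and a restriction to genes at or above the median level, were added after seeing the data.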

Results

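The 6 arrays asked which transcripts differ in 786-O renal carcinoma cells when ERCC6L, a DNA translocase also known as PICH that binds the DNA threads joining sister chromatids in anaphase, is reduced by RNA interference. There were 3 arrays per group. Correlations of log2(signal + 16) lay between 0.9987 and 0.999 within groups and between 0.9932 and 0.9939 across groups, and the median standard deviation within groups was 0.0517 on the log2 scale. Median signals per array were 60.37 to 61.56 in shNC and 60.04 to 61.21 in shERCC6L.

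The target transcript was lower on every shERCC6L array. The single ERCC6L probe set read 239.9, 244.3 and 261.4 on the shNC arrays and 97.59, 97.49 and 97.83 on the shERCC6L arrays, so that 39.3% of the control signal was left. The log2 fold change was -1.22 ± 0.04 (SE, n = 3 per group; limma adjusted p = 1.6e-07). ERCC6L lies on chromosome X from 72204665 to 72239027 (GRCh38.p14). Among genes at or above the median level, the 4 next to it in genome order were looked up for their position alone. PIN4, whose interval spans that of ERCC6L, RPS4X and HDAC8 did not pass, at log2 fold changes of 0.09, -0.00 and -0.04, while OGT fell by 0.33 (adjusted p = 0.00012).

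Changes were many and mostly small, and the large ones were mostly falls. Of 18132 genes, 5733 (31.6%) passed the threshold, 3302 higher and 2431 lower in shERCC6L, with a median absolute log2 change of 0.235. Only 74 of them changed by at least 2-fold, 12 up and 62 down. At 1.5-fold the counts were 129 up and 249 down. The groups did not overlap for 7875 genes (43.4%), where chance gives 10% if the arrays are independent. The labels do not say whether they are, so any difference between the cultures could add to this share and to the calls. When each gene's probe sets were averaged, 45 genes changed by at least 2-fold, 6 up and 39 down. With a pseudocount of 1 there were 96, 23 up and 73 down, and the share of falls went from 83.8% to 76%. Averaging also moved the log2 fold change of 14 of the genes named by rule by a factor of 1.5 or more, in each case towards 0, and no other alternative did so for a gene named by rule.

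**Figure D1:**
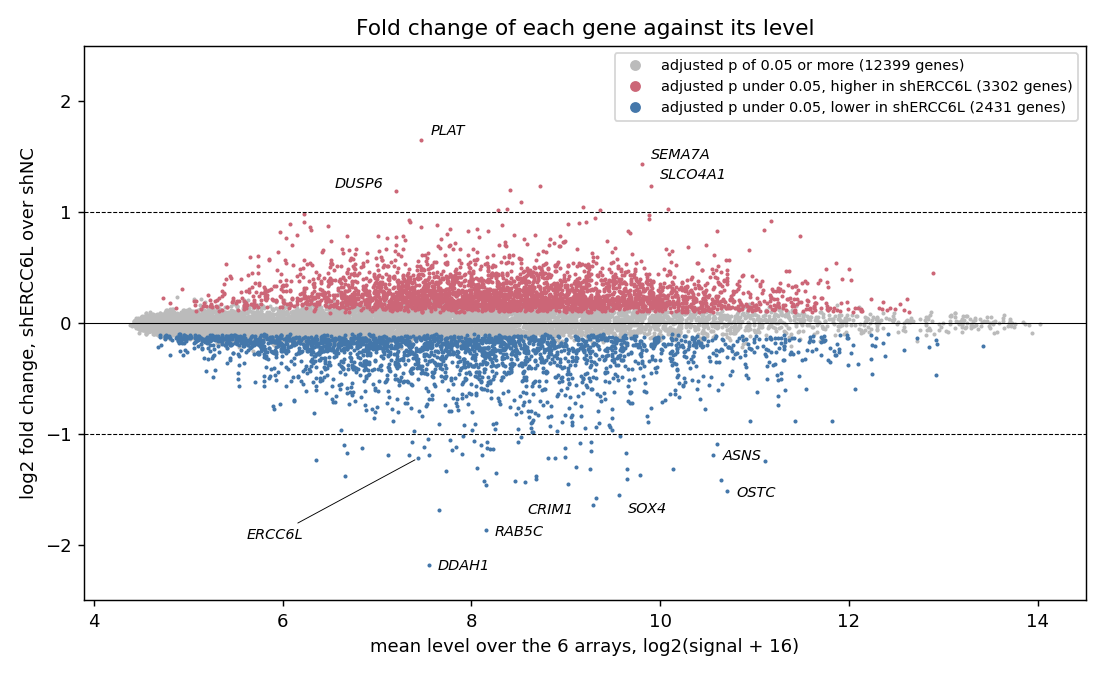
Fold change of each of the 18132 genes (y axis, log2, shERCC6L over shNC) against its mean level over the 6 arrays (x axis, log2(signal + 16)); colour marks the 3302 higher and 2431 lower genes past adjusted p = 0.05, and dashed lines mark a 2-fold change. Below the lower line lie 62 called genes and above the upper line 12.

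On each gene's brightest probe set PLAT, which encodes tissue plasminogen activator, rose most, from a signal of 84 ± 4.95 to 298.6 ± 28.1 (SD, n = 3 per group), a log2 fold change of 1.65 ± 0.06 (SE). SEMA7A, a membrane-anchored semaphorin, rose 2.70-fold to 1459, and the organic anion transporter gene SLCO4A1 rose 2.36-fold. MZT1, a subunit of the gamma-tubulin complexes that nucleate spindle microtubules, rose 2.35-fold and GSKIP, which encodes a partner of the kinase GSK3-beta, 2.30-fold. DUSP6, the phosphatase that switches off ERK, rose from 81.71 ± 5.03 to 206.5 ± 11.3. The other 6 of the 12 rises were PSPC1 (2.13-fold), TMEM158 (2.07-fold), NAA15 (2.04-fold), ARL2BP (2.04-fold), the fatty acid elongase ELOVL6 (2.03-fold) and the deubiquitinase OTUB2 (2.02-fold). All 12 had adjusted p-values of 4.5e-06 or less. Of the 4 other PSPC1 probe sets, 2 rose and 1 fell, and 6 of the 12 rises were under 2-fold with probe sets averaged. Their averaged log2 fold changes were 0.41 for PSPC1, 0.76 for ARL2BP, 0.85 for NAA15, 0.90 for OTUB2, 0.92 for ELOVL6 and 0.95 for SEMA7A. ARL2BP, NAA15, OTUB2 and ELOVL6 also lay under 2-fold in other alternatives, at 0.94 or more, quantile normalization among them for all but NAA15.

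On the brightest probe sets DDAH1, an enzyme that degrades asymmetric dimethylarginine, fell most, from 383 ± 17.7 to 72.06 ± 4.45 (SD, n = 3 per group), a log2 fold change of -2.18 ± 0.05 (SE). RAB5C, a GTPase of early endosomes, was 3.65-fold lower. With each gene's probe sets averaged RAB5C fell by more than DDAH1, with log2 fold changes of -1.78 and -1.43. RNF130 was 3.21-fold, CRIM1 3.11-fold and SELENOT, a selenoprotein of the endoplasmic reticulum, 2.98-fold lower. The transcription factor gene SOX4 fell from 1281 to 426.8, or 2.93-fold, on all 7 of its probe sets. OSTC, a subunit of the oligosaccharyltransferase that glycosylates nascent proteins, was 2.86-fold and MMGT1 2.76-fold lower. YAP1, the transcriptional coactivator of the Hippo pathway, was 2.74-fold lower, and all 8 of its probe sets fell. NETO2 (2.70-fold), ARHGAP1 (2.69-fold) and PRKACB, a catalytic subunit of protein kinase A (2.68-fold), completed the 12. Their adjusted p-values were 4.2e-07 or less. Of the 3 other PRKACB probe sets, 2 fell and 1 rose, and with probe sets averaged the log2 fold changes were -0.73 for PRKACB and -0.95 for SELENOT, both under 2-fold.

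**Figure D2:**
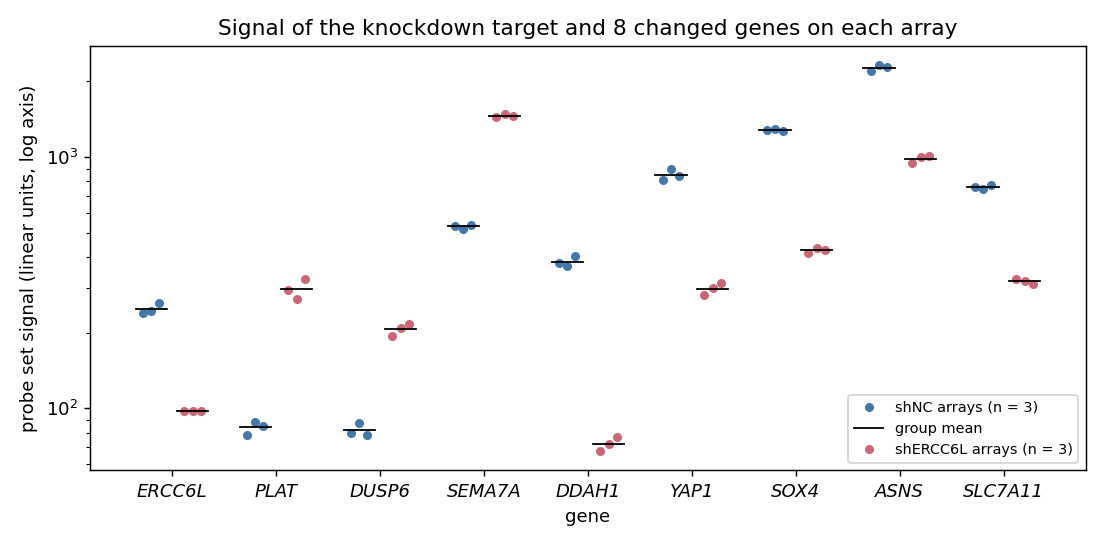
Linear probe set signal (y axis, log axis) of ERCC6L and 8 changed genes (x axis) on each of the 3 shNC and 3 shERCC6L arrays, with the group mean as a bar. The groups do not overlap for any of these genes: ERCC6L read 239.9 to 261.4 on shNC arrays and 97.49 to 97.83 on shERCC6L arrays.

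Of the 36 gene lists, 14 passed camera's threshold with the preset correlation, 10 higher and 4 lower in shERCC6L. With an estimated correlation camera called 0 lists, with 7 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.184. That setting also tests on the 4 residual degrees of freedom, so the few arrays raise its p whatever the correlation. The cholesterol estimate of -0.029 lay below the preset, yet its unadjusted camera p rose from 0.00019 to 0.0154. The mitosis estimate, 0.127, lay above the preset. The 0 calls therefore do not separate correlation from few arrays. A different question, whether a list's genes moved on balance one way without regard to other genes, was put to fry, which called 24. Among the 9066 genes at or above the median level, adjusted among themselves, 3289 were higher and 1999 lower. Most of the 14 lists hold mainly genes at that level, so their counts are best read against these. Beside each of the 14 lists stand its p with an estimated correlation and the range of camera's adjusted p over the alternatives. The low end of that range was mostly reached where every probe set was counted, so that a gene entered more than once.

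In the mitosis and chromosome segregation list, 31 of 41 measured genes were higher and 3 lower (32 and 3 adjusted over the list alone, median log2 fold change 0.237, camera adjusted p = 6.2e-10, adjusted p = 0.184 with an estimated correlation, range 1.2e-12 to 0.184). BIRC5, the survivin subunit of the chromosomal passenger complex, rose by 0.66 ± 0.03 (log2, SE), the spindle kinase gene AURKA by 0.57 ± 0.04 and CDC20, an activator of the anaphase-promoting complex, by 0.47 ± 0.03. With probe sets averaged the changes were 0.41 for BIRC5 and 0.30 for CDC20. HMMR, which encodes a spindle-associated hyaluronan receptor, fell by 0.60 ± 0.03. ASPM and KIF20A were the other members that fell, by 0.24 and 0.12. CCNA2 and MAD2L1, at 0.01 and 0.03, did not pass.

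In the anaphase bridge resolution list, 6 of 15 genes were higher and 1 lower (7 and 1 adjusted over the list alone, median log2 fold change 0.105, camera adjusted p = 0.0113, adjusted p = 0.184 with an estimated correlation, range 1.1e-05 to 0.234). TOP2A, the topoisomerase that unlinks sister chromatids, rose by 0.39 ± 0.04, the Bloom helicase gene BLM by 0.45 ± 0.05 and PLK1 by 0.26 ± 0.04, while NSMCE2 fell by 0.26 ± 0.04. This call ended among genes at or above the median level (adjusted p = 0.234, median 0.084) and without the dimmest genes (0.0712, median 0.105). TOP2A and PLK1 also stand in the mitosis list. The share of members that rose was near that of all genes at or above the median level, while fewer fell.

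Of 36 genes of DNA replication and S phase, 20 were higher and 2 lower (20 and 2 adjusted over the list alone, median log2 fold change 0.167, camera adjusted p = 1.4e-04, adjusted p = 0.252 with an estimated correlation, range 1.3e-07 to 0.252). RRM2, a subunit of ribonucleotide reductase, rose by 0.38 ± 0.03, MCM10 by 0.48 ± 0.04 and the flap endonuclease gene FEN1 by 0.36 ± 0.03. PRIM1, the DNA primase subunit, fell by 0.45 ± 0.04, as did TYMS, by 0.23. Of the 24 replication-dependent histone genes 0 were higher and 1, H1-2, was lower (0 and 1 adjusted over the list alone, median -0.016, camera adjusted p = 0.741), but only 3 of them reached the median level. The p53 targets divided, with 8 higher and 6 lower of 26 (10 and 7 adjusted over the list alone, camera adjusted p = 0.638). GDF15 fell by 0.57 ± 0.04, the death receptor gene TNFRSF10B rose by 0.49 ± 0.05, and PLK3 and AEN rose by 0.34 and 0.38. CDKN1A rose by 0.11 ± 0.04.

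Of 25 ERK-responsive genes, 16 were higher and 3 lower (17 and 4 adjusted over the list alone, median log2 fold change 0.231, camera adjusted p = 7.4e-06, adjusted p = 0.184 with an estimated correlation, range 2.3e-11 to 0.184). Beside DUSP6, the AP-1 gene FOSL1 rose by 0.95 ± 0.04, the ERK phosphatase gene DUSP5 by 0.81 ± 0.04 and the ETS factor gene ETV5 by 0.76 ± 0.04. MYC, LIF and SPRED2 fell, by 0.28, 0.15 and 0.38, and the immediate early genes FOS and EGR1, at 0.03 and 0.02, did not pass. Among 32 MAPK pathway components 10 were higher and 10 lower (11 and 10 adjusted over the list alone, median 0.015; camera adjusted p = 0.902). RPS6KA5 rose by 0.83 ± 0.06 and MAP2K3 by 0.64 ± 0.06, while MAP3K1 fell by 0.45 ± 0.04. MKNK2 fell by 0.46 ± 0.04 on its brightest probe set, but 1 of its 4 others rose, and with its probe sets averaged the change was -0.03 and did not pass.

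In the integrated stress and unfolded protein response list 18 of 32 genes were lower and 4 higher (20 and 5 adjusted over the list alone, median log2 fold change -0.188, camera adjusted p = 7.4e-05, adjusted p = 0.184 with an estimated correlation, range 7.6e-15 to 0.184). SLC7A11, the cystine transporter, fell from 761.4 ± 14.2 to 320 ± 7.75 (SD, n = 3 per group), 2.31-fold, and ASNS, asparagine synthetase, from 2269 ± 61.5 to 985.3 ± 37.1, 2.28-fold. With probe sets averaged the log2 fold change of SLC7A11 was -0.94, under 2-fold. SLC3A2, the heavy chain that partners SLC7A11, fell by 0.54 ± 0.04 (log2, SE) and ATF4, the transcription factor of this response, by 0.38 ± 0.03. The members that rose were the endoplasmic reticulum genes EDEM1, SDF2L1, DNAJC3 and MANF. Aminoacyl-tRNA synthetases were lower for 8 and higher for 5 of 19 (9 and 5 adjusted over the list alone, camera adjusted p = 0.385).

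Of 15 heat shock protein genes, 12 were higher and 1 lower (13 and 1 adjusted over the list alone, median log2 fold change 0.243, camera adjusted p = 1.1e-05, adjusted p = 0.184 with an estimated correlation, range 3.1e-15 to 0.184). The constitutive chaperone gene HSPA8 rose by 0.46 ± 0.03, HSP90AA1 by 0.36 ± 0.03, HSPH1 by 0.35 ± 0.04 and the inducible HSPA1B, which has a near-identical neighbour copy whose signal may not be separable, by 0.32 ± 0.04. HSPB1 fell by 0.11, but 0 members passed as lower with quantile normalization or with median centring. Genes of ribosome biogenesis were higher for 15 and lower for 1 of 21 (17 and 1 adjusted over the list alone, median log2 fold change 0.195, camera adjusted p = 2.8e-06, adjusted p = 0.184 with an estimated correlation, range 3.8e-10 to 0.184). The rRNA methyltransferase gene NOP2 rose by 0.38 ± 0.04, the RNA polymerase I and III subunit POLR1C by 0.43 ± 0.05, NOP16 by 0.36 ± 0.04 and RRS1 by 0.35 ± 0.04, and the member that fell was MYC. The mRNAs of cytosolic ribosomal proteins were higher for 0 and lower for 1, RPL13, of 30 (0 and 1 adjusted over the list alone, camera adjusted p = 0.603). Their median was -0.014, and 0.013 with quantile normalization.

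Cholesterol biosynthesis genes were higher for 12 and lower for 0 of 19 (13 and 1 adjusted over the list alone, median log2 fold change 0.171, camera adjusted p = 9.8e-04, adjusted p = 0.184 with an estimated correlation, range 2.3e-08 to 0.184). With quantile normalization 9 were higher and 1 lower (median 0.138), and with median centring 12 and 0. HMGCS1, the synthase at the entry of the mevalonate pathway, rose by 0.68 ± 0.04, the squalene epoxidase gene SQLE by 0.54 ± 0.03, MSMO1 by 0.42 ± 0.03 and IDI1 by 0.56 ± 0.07. The call ended among genes at or above the median level (adjusted p = 0.0737), at a median of 0.145. Fatty acid synthesis and lipid storage genes were higher for 6, ELOVL6 among them, and lower for 3 of 18 (8 and 3 adjusted over the list alone, camera adjusted p = 0.374).

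The matrix, TGF-beta and YAP-TAZ lists were lower relative to other genes, although most members of the matrix and YAP-TAZ lists did not pass as lower. Of 34 extracellular matrix and remodelling genes, 14 were lower and 4 higher (14 and 5 adjusted over the list alone, median log2 fold change -0.054, camera adjusted p = 0.0071, adjusted p = 0.268 with an estimated correlation, range 0.000306 to 0.268). The fibrillin gene FBN1 fell by 0.91 ± 0.04, COL8A1 by 0.64 ± 0.03, and the metalloproteinase genes MMP2 by 0.63 ± 0.04 and MMP7 by 0.75 ± 0.05. None of the other 2 COL8A1 probe sets and only 1 of the other 4 FBN1 probe sets passed. With probe sets averaged the log2 fold changes were -0.16 for COL8A1 and -0.39 for FBN1. The list median ran from -0.125 without the dimmest genes to -0.034 with probe sets averaged. Of 18 TGF-beta targets, 10 were lower and 3 higher (10 and 3 adjusted over the list alone, median log2 fold change -0.154, camera adjusted p = 0.0322, adjusted p = 0.229 with an estimated correlation, range 0.00216 to 0.229). ID3, an inhibitor of basic helix-loop-helix factors, fell by 0.83 ± 0.03 and the ligand gene TGFB2 by 0.73 ± 0.04, while INHBA rose by 0.63 ± 0.03 and ANGPTL4 by 0.70 ± 0.06. Its median ran from -0.165 with the background covariate to -0.044 with every probe set counted. Without shNC replicate 2 this list did not pass (adjusted p = 0.0594, median -0.149), nor among genes at or above the median level (adjusted p = 0.0737, median -0.154).

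Of 20 YAP-TAZ targets, 9 were lower and 4 higher (9 and 4 adjusted over the list alone, median log2 fold change -0.02, camera adjusted p = 0.0373, adjusted p = 0.306 with an estimated correlation, range 0.00229 to 0.306). The mean was -0.212, farther from 0 than the median, and the median itself ran from -0.24 among genes at or above the median level to -0.01 without shNC replicate 1. Besides CRIM1 and TGFB2, GADD45B fell by 0.63 ± 0.04 and the receptor kinase gene AXL by 0.50 ± 0.04, though the other AXL probe set did not pass. With probe sets averaged the changes were -0.39 for GADD45B and -0.23 for AXL. CCN2 and ANKRD1, at -0.02 and -0.01, did not pass. The list missed the threshold with a replicate block (adjusted p = 0.0518), with array weights (0.0528), with a pseudocount of 1 (0.0585), and without shNC replicate 2 or shERCC6L replicate 1 (0.0594 in both). Integrins and focal adhesion genes were lower for 9 and higher for 5 of 23 (9 and 5 adjusted over the list alone, camera adjusted p = 0.107), and genes of epithelial-mesenchymal transition lower for 7 and higher for 3 of 19 (7 and 4 adjusted over the list alone, camera adjusted p = 0.217). The mesenchymal marker VIM, at -0.00, did not pass.

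**Figure D3:**
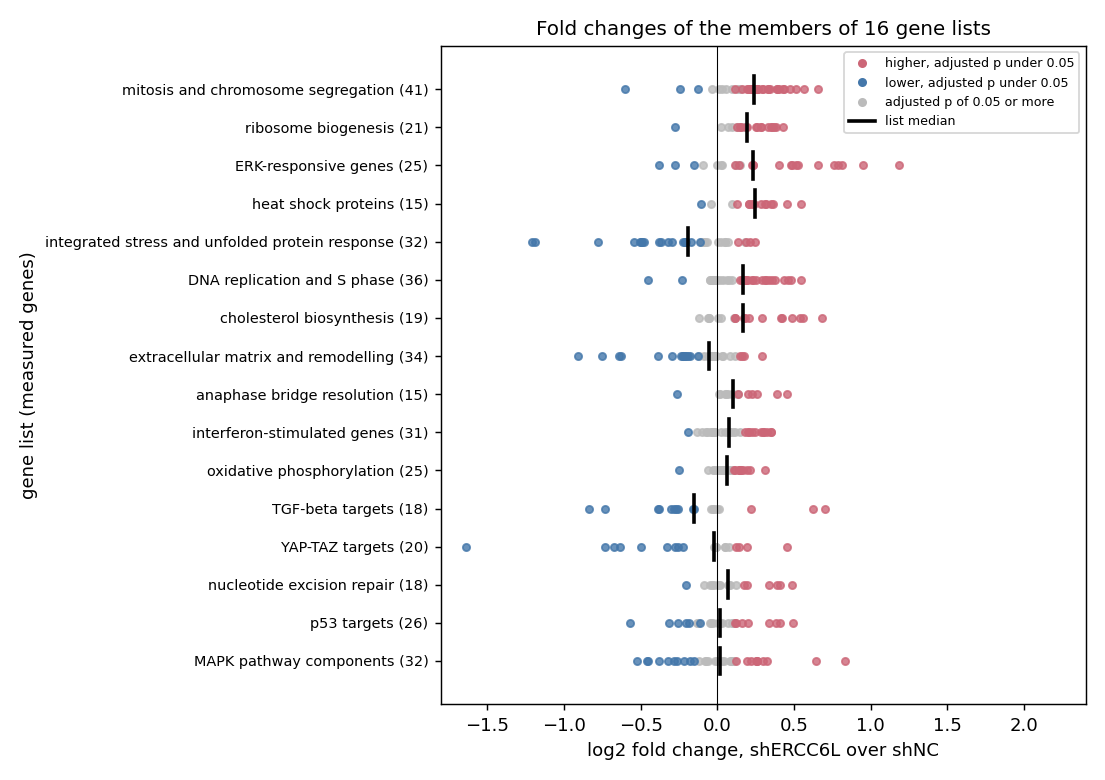
Log2 fold change (x axis, shERCC6L over shNC) of each measured member of 16 gene lists (y axis, with the number of measured genes): the 14 past camera's threshold, then p53 targets and MAPK pathway components. Each point is a gene, coloured where it passed adjusted p = 0.05, and black bars are list medians, from 0.243 for heat shock proteins to -0.188 for the stress response list.

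The remaining lists past the threshold had small medians. In the oxidative phosphorylation and repair lists the share of rises was near that of all genes at or above the median level, while fewer fell. Interferon-stimulated genes were higher for 11 and lower for 1 of 31 (11 and 1 adjusted over the list alone, median log2 fold change 0.078, camera adjusted p = 0.0186, adjusted p = 0.252 with an estimated correlation, range 0.0104 to 0.252), led by IFI6 (0.35 ± 0.03), SAMD9 (0.35 ± 0.05), ISG15 (0.31 ± 0.04) and IFI44 (0.30 ± 0.04), while IFIT1 fell by 0.19. Only 1 of the 5 other IFI44 probe sets passed, and with its probe sets averaged the change was 0.13. The list median ran from 0.032 with every probe set counted to 0.199 among genes at or above the median level. Without the dimmest genes the adjusted p was 0.0501, just short of the threshold, at a median of 0.114. Oxidative phosphorylation genes were higher for 10 and lower for 1 of 25 (11 and 1 adjusted over the list alone, median log2 fold change 0.064, camera adjusted p = 0.0204, adjusted p = 0.325 with an estimated correlation, range 0.00382 to 0.325). ATP5MC1, NDUFB8 and NDUFS1 rose by 0.31, 0.21 and 0.17 and NDUFV2 fell by 0.25. The other NDUFB8 probe set did not pass. Nucleotide excision repair genes were higher for 6 and lower for 1 of 18 (6 and 1 adjusted over the list alone, median log2 fold change 0.072, camera adjusted p = 0.0483, adjusted p = 0.325 with an estimated correlation, range 0.0203 to 0.325), with CETN2, GTF2H3, ERCC4 and RPA3 up by 0.49, 0.39, 0.41 and 0.33. Only 1 of the 4 other ERCC4 probe sets passed, and with its probe sets averaged the change was 0.15. The oxidative phosphorylation and repair calls ended with quantile normalization (adjusted p = 0.0586 and 0.178), among genes at or above the median level (0.239 and 0.269), without the dimmest genes (0.133 and 0.16), with probe sets averaged (0.0601 and 0.067) and with the background covariate (0.0619 and 0.0782). The repair call also ended with a pseudocount of 1 (0.0511). With quantile normalization the oxidative phosphorylation median was 0.062 and the repair median 0.035, so that the repair change itself shrank. With probe sets averaged the oxidative phosphorylation median was 0.034 and the repair median 0.066. Over all alternatives the medians lay between 0.034 and 0.079 for oxidative phosphorylation and between 0.035 and 0.083 for repair. Leaving out shERCC6L replicate 3 ended both (0.0624 and 0.0727), and the repair call ended without shNC replicate 2 (0.057), shNC replicate 3 (0.0558) or shERCC6L replicate 2 (0.0828).

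Other lists did not pass camera's threshold and held changes in both directions. NF-kB and inflammatory cytokine genes were higher for 12 and lower for 6 of 25 (13 and 6 adjusted over the list alone, camera adjusted p = 0.101): IL6 rose by 0.73 ± 0.04, CXCL2 by 0.83 ± 0.04 and CXCL8 by 0.54 ± 0.03, and CCL2 fell by 0.44 ± 0.05. Hypoxia-inducible factor targets, of interest in this VHL-deficient line, were higher for 9 and lower for 7 of 24 (9 and 7 adjusted over the list alone, adjusted p = 0.802). EPAS1, which encodes HIF-2 alpha, fell by 0.36 ± 0.03 and VEGFA rose by 0.11 ± 0.03. Apoptosis regulators were higher for 9 and lower for 7 of 26 (11 and 7 adjusted over the list alone, adjusted p = 0.603), and PI3K-AKT-mTOR components higher for 8 and lower for 7 of 25 (9 and 7 adjusted over the list alone, adjusted p = 0.851), with a median of 0.005 and a mean of -0.003. With quantile normalization 7 of these were higher and 8 lower. Glycolysis genes were higher for 3 and lower for 4 of 18 (3 and 4 adjusted over the list alone, adjusted p = 0.741). Autophagy and lysosome genes were lower for 7 and higher for 4 of 24 (8 and 4 adjusted over the list alone, adjusted p = 0.155), with MAP1LC3B, the LC3B precursor, down by 1.16 ± 0.05. NRF2 targets were lower for 6 and higher for 4 of 18 (7 and 4 adjusted over the list alone, adjusted p = 0.447, median -0.001 and 0.01 with quantile normalization), and small RNA pathway genes lower for 4 and higher for 3 of 13 (4 and 3 adjusted over the list alone, adjusted p = 0.741). Housekeeping genes were higher for 3 and lower for 1 of 12 (3 and 1 adjusted over the list alone, adjusted p = 0.331). The transferrin receptor gene TFRC, counted among them, rose by 0.84 ± 0.04, while ACTB, GAPDH and B2M, at -0.04, 0.01 and 0.00, did not pass, nor with quantile normalization or median centring.

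Markers of other cell types showed few changes, but most were dim, which by itself leaves few changes to be seen. At or above the median level lay 4 of 17 leukocyte, 1 of 11 endothelial and 1 of 5 erythroid genes. Of the fibroblast and smooth muscle genes 0 of 13 did, and of the renal tubule genes 5 of 18. The leukocyte list had 1 higher gene, CD68, of 17 (camera adjusted p = 0.815), the endothelial list 1 lower, TIE1, of 11 (0.347, and 0 lower with median centring), the erythroid list 0 of 5 (0.603) and the fibroblast and smooth muscle list 3 lower of 13, COL1A1, ACTA2 and PDGFRA (0.107); adjusted over the list alone the counts were 1, 0, 0 and 3. Renal tubule markers were higher for 2, PAX8 and LHX1, and lower for 2, CDH6 and CDH16, of 18 (the same counts adjusted over the list alone; 0.741). The 3' to 5' log2 difference of the ACTB controls was -0.02 ± 0.031 in shNC and -0.015 ± 0.036 in shERCC6L (SD, n = 3 per group; exact permutation p = 0.8, 2-sided), and that of the GAPDH controls -0.059 ± 0.011 and -0.064 ± 0.011 (exact permutation p = 0.5). With 3 against 3 arrays such a test cannot go below 0.1.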

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

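The checks of array scaling and of a pseudocount of 1 on the direction of the large changes, of the histone genes and of the branches of the stress response were chosen after the result they bear on was seen. The covariate for array background was added after the data had been seen, but before its own result was.

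Signal outside the comparisons was seen in probe sets with no gene listed or with several genes. Of these 4305 probe sets, 1125 passed adjusted p = 0.05, and 2 were at least 2-fold higher and 3 at least 2-fold lower in shERCC6L than in the shNC controls. Of the 45 spike-in control probe sets, 2 (4.44%) passed, the largest with an absolute log2 change of 0.176. Among the called genes, 4139 changed by more than that, 2476 up and 1663 down.

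Of the 10 splits of the 6 arrays into 3 and 3, only the real one (1 of 10) gave 5733 genes past the threshold, and only it (1 of 10) gave 74 genes changed at least 2-fold. The highest other split gave 0 by limma, with at most 682 genes at an unadjusted p under 0.05. Every other split puts arrays of both groups on each side, so the group difference widens the spread there and holds calls down. The contrast with 5733 therefore does not measure what chance would give. So few splits cannot give a share under 0.05.

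Most genes changed by at least 2-fold fell, 62 of 74. Scaling done before deposit could not be tested. A scale difference left between the deposited arrays is argued against, since the share of falls was at least 83.8% after quantile normalization or median centring. So is a floor under dim signals as the whole cause, since 58 of the 70 such genes at or above the median level fell, which is 82.9%. A pseudocount of 1 lowered the share of falls over all genes from 83.8% to 76% (73 of 96), and at or above the median level it was 82.3% (65 of 79). The size of the excess thus depends on how dim signals are treated, and changed little among genes at or above the median level. Also argued against are single deviant probe sets, since 88.1% (141 of 160) of the other probe sets of these genes moved the same way and 3 moved the opposite way. That check covers direction, not size: with probe sets averaged, only 40 of the 74 genes stayed at least 2-fold changed. A candidate explanation that stays open is repression of transcripts other than ERCC6L by the hairpin, which could not be tested because the labels give no hairpin sequence and no transcript sequences were used here. A response to the loss of ERCC6L itself, the difference the design names, also stays open and untested.

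The mitosis list was higher although ERCC6L is itself a mitotic gene. Its median log2 fold change of 0.237 was 0.21 or more under quantile normalization and median centring. With a covariate for array background it was 0.216. This argues against array background, and against a scale difference left in the deposited values, as the whole cause. A difference in growth or density between the cultures cannot be told apart from the knockdown. The replication-dependent histones, with a median of -0.016, cannot decide this: only 3 of the 24 reach the median level, and the design holds a single contrast. The list's call was also lost with an estimated correlation (camera adjusted p = 0.184), a setting that has fewer degrees of freedom as well.

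Within the stress response list the branches came apart. Of 20 genes of the ATF4 branch, 15 were lower and 0 higher (limma, median -0.309), whereas of 12 endoplasmic reticulum genes 3 were lower and 4 higher (median 0.037). The medians differed with a 2-sided permutation p of 0.00367 across genes, which are not independent replicates. As the split was made after the list result was seen, this p describes the difference. It is no independent argument against a fall of both branches alike. The endoplasmic reticulum genes that fell were HERPUD1, HSPA5 and XBP1, by 0.49, 0.21 and 0.21. TRIB3, at 0.05, was among the genes of the ATF4 branch that did not pass. A difference in nutrient state between the cultures and an effect of the knockdown both stay open, since no array separates them.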

How the results depend on the processing

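The background covariate and the restriction to genes at or above the median level were chosen after seeing the data. ERCC6L stayed lower and past the threshold under all 17 alternatives (log2 fold change -1.34 to -1.18; -1.24 to -1.18 when 1 array was left out). Of the other named genes' values, 1443 kept their direction and side of the threshold, and 1 did not, MKNK2 with probe sets averaged (-0.03). Without 1 array, the called genes numbered 4694 to 5378 (2783 to 3125 higher, 1911 to 2253 lower), those changed at least 2-fold 71 to 78 (11 to 14 higher, 60 to 67 lower), and the lists past the threshold 11 to 14. The replicate numbers did not pair the arrays; a replicate block gave 5619 genes, 5353 of them among the 5733, and the same 74 changed at least 2-fold. At least 2-fold changes numbered 45 (6 higher, 39 lower, 40 of them among the 74) with probe sets averaged, and 23 were higher with a pseudocount of 1. Testing every probe set gave 13047 (7643 higher, 5404 lower), and 179 at 2-fold (40 and 139), because more features were counted. A threshold of 1.5-fold gave 378 (129 and 249), and adjusted p under 0.01 gave 1553 lower genes of 3931. Quantile normalization gave 5614 genes, 47.1% of them lower against 42.4%. The number of lists past the threshold went from 14 to 0 with an estimated correlation and to 9 among genes at or above the median level, where the median of all genes was 0.036. Fry, which does not compare a list with other genes, called 24. Of the 41 cases in which a called list kept its direction and missed the threshold, 14 were with an estimated correlation. The MAPK list, never called, had a median of -0.004 without shNC replicate 2 and -0.038 without shERCC6L replicate 3 (-0.038 to 0.0534 without 1 array), and -0.0365 with the background covariate; the p53 list, never called, had -0.012 among genes at or above the median level. Except where stated, the cause was not tested. The 3 arrays per group limit the detection of small changes. In simulation 62% of changes of 0.25 were recovered, but with only 193 calls. With 5733 genes called the adjusted threshold is less strict, so that share does not carry over to these data.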

Other observations

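The grouping of genes by symbol was chosen after the main results were seen, and so was the comparison of the neighbour value with the spread of the shuffled orders. Genes were also grouped by the root of their symbol, with at least 8 members at or above the median level, and 139 such families were tested against the 9066 genes at that level. Mitochondrial ribosomal proteins of the large subunit (MRPL) were the 1 family past camera's threshold: 33 of 48 were higher and 0 lower (median log2 fold change 0.173 against 0.036 for all genes at that level, adjusted p = 0.0023, and adjusted p = 0.806 with an estimated correlation). MRPL35 rose by 0.36 ± 0.03 (SE), MRPL49 by 0.32 ± 0.03 and MRPL15 by 0.26 ± 0.03 (limma, n = 3 per group). With quantile normalization 25 were higher and 0 lower (median 0.139). Of 27 small subunit genes (MRPS) 13 were higher and 1 lower, without passing as a family (adjusted p = 0.143), and MRPS23 rose by 0.54 ± 0.03.

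The next 3 families had the same camera adjusted p of 0.0951, short of the threshold. Genes of the WDR root were higher for 23 and lower for 1 of 41 (median 0.173, and 0.152 with quantile normalization). Matrix metalloproteinases were lower for 6 and higher for 2 of 11 (median -0.189, and -0.212). Aldehyde dehydrogenases were lower for 8 and higher for 0 of 12 (median -0.193, and -0.226). ALDH1A1 fell by 0.50 ± 0.07 and ALDH3B1 by 0.41 ± 0.04.

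The shNC and shERCC6L cells could differ in copy number along a chromosome, which would move neighbouring genes together. Over 9066 genes in the order of GRCh38.p14, the largest absolute median over 51 neighbours was 0.144 relative to all genes, against a 95th percentile of 0.145 over 1000 shuffled orders (permutation p = 0.059). A bound of 0.2 had been set before the value was seen, and 0.144 lies under it by 0.056. The median and the 95th percentile of the shuffled orders lay 0.025 apart, which is the spread of a largest value. It is not the error of a window's median, so how far a true shift of 0.2 could read low was not measured. By the bound alone, the value argues only weakly against a copy number difference that moves 51 neighbouring genes by 0.2 or more. Smaller or shorter differences are not excluded either. Neighbouring genes correlated slightly, with r = 0.019 across genes, which are not independent replicates (permutation p = 0.037).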
